A study of Mus musculus with 22 samples.

How the data were processed

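Kidney RNA of male C57BL/6 mice was profiled with a targeted amplicon panel for the mouse transcriptome (Ion AmpliSeq) and read on an Ion Proton sequencer, per the labels' protocols. In such a panel, gene-specific primers amplify a short stretch of each target transcript. RNA input was 300 to 500 ng per library, per the labels' protocols. The reads were mapped to the transcriptome supplied with the panel for the mouse build mm10, per the labels' protocols, and mm10 is also the build in the submitters' processing notes. The counting tool, its version and its filters are not given in the sources used here. The authors deposited 1 table of the whole series, whose name gives its values as FPKM, a fragment count scaled to transcript length and to the number of mapped fragments. The deposited table has 121562 rows, 1 per RefSeq transcript. Of these rows 78571 (64.6%) are computationally predicted transcript models, 36592 are curated messenger RNAs and 6399 are curated non-coding RNAs. Which rows are targets of the panel was not established. Counts over all genes, and shares of non-coding RNAs, can therefore include genes without a primer pair. The 13 mitochondrially encoded genes on a list fixed beforehand matched no row by name and were not analysed here.

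The table has 23 columns, each named by an Ion barcode between 0109 and 0131, and the series describes 22 samples. All 22 sample descriptions name the same barcode, 0109. No barcode therefore matched 1 sample or 1 group by name, and 0 columns were matched to a sample. The sample titles carry running numbers with 1 number left out, and the barcodes also run in sequence. Pairing them would be an inference from order and was not made. With 23 libraries and 22 described samples, at least 1 library has no described sample, and which one was not established. The planned comparisons (age in vehicle-treated mice, the agonist in old and in young mice, their interaction, and the tests of gene lists and of reversal), which had been fixed before the data were examined, were for this reason not made. All statements below are about the 23 barcoded libraries, each given as its own value or as a median and range, without a standard deviation.

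The FPKM values that the authors deposited had an unusual structure, which was used to recover the number of reads that the table holds. Within a library, values were mostly whole multiples of 1 step (the most frequent value above 0), and the step was the same for transcripts of very different length. Across the libraries 616 transcripts lay within 0.01 of 1 step in at least 1 library. Of these, 292 had a matched GENCODE M21 transcript, with lengths from 86 to 13934 nt. The step was taken as the value of 1 read, and each value was divided by it to give reads. A median of 65.7% of the values above 0 (range 55.4% to 72.0%) were whole within 0.01 read, and these values held a median of 95.0% of the reads (range 88.2% to 97.0%). The remaining 2431 values were not whole, 1951 of them below 1 step and 480 above it. The division gave a median of 1788 reads per library (range 1187 to 4131) and 47118 reads over all libraries. That the step is 1 read is an inference from the values. The number of reads sequenced per library, or used by the authors for scaling, is not given in the sources used here, and the reads in the table are not shown to be the library's whole depth.

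Rows were summed per gene. Gene symbols came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10, which matched 117213 rows (96.4%), and otherwise from the row's own name, giving 39072 genes. Gene coordinates are from that table. The position of the counted reads within a transcript is not given. A gene's share is its percentage of the library's reads in the table. Shares of a single library have 95% Wilson binomial intervals. The panel reads carry no molecular identifiers that are described here, so intervals and tests cover counting error only.

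For each gene with a mean of at least 5 reads per library, a chi-square test compared the gene's reads with all other reads of the 23 libraries (22 degrees of freedom). The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. This test asks whether libraries differ, and makes no statement about conditions. On simulated libraries with the same numbers of reads, in which 10 genes were changed in alternate libraries and the share of Pck1 gave way, the test called 10% of genes changed 1.5-fold, 90% of those changed 2-fold and 100% of those changed 3-fold, and 0 unchanged genes. These steps tested 53, 56 and 53 genes other than Pck1, with 1 draw of changed genes per fold. Where no gene gave way and the 10 changed genes again had low shares, the test called 0 of 45, 1 of 42 and 1 of 44 unchanged genes at 1.5-, 2- and 3-fold. Where 20 genes of any share other than Pck1 were changed, it called 40%, 65% and 90% of them, and 0 of 35, 3 of 32 and 20 of 33 unchanged genes. The shares of a library add up to the whole, so a change of abundant genes shifts the shares of all others, in the real libraries as well. Libraries in which Pck1 changed and the shares of all other genes followed were not simulated. Pairs of libraries were compared by chi-square over the same genes and the remaining reads, with the same adjustment over pairs. Correlations across libraries used log2 of (reads + 0.5) over all reads other than Pck1, with Pearson's r and Spearman's rho and 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

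The 62 gene lists were fixed before the data were examined. The rule for named genes fixed beforehand chose genes by comparison and applied here only to the receptors and to list members. The 20 genes with the highest median share were named in its place, a rule chosen after the values were seen, as were the ubiquitous and kidney genes looked up at 0 and the genes outside these sets that are named below. Some genes looked up are not reported here. Of the alternatives in processing, 3 changed the rows or values used (whole values only, messenger RNA rows only, without Rmrp), others changed thresholds, and 1 left out each library in turn. All of these were chosen after seeing the data.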

Results

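The series concerns estrogen-related receptors (ERRs), orphan nuclear receptors that regulate genes of mitochondrial energy metabolism, in the ageing kidney. It asks, by its title and design, how a pan-ERR agonist acts on mitochondrial and inflammatory genes in old mice. The agonist, SLU-PP-332, was given by intraperitoneal injection at 25 mg per kg body weight per day for 8 weeks, and control mice received a vehicle with 3% DMSO. The labels describe 6 young vehicle-treated, 6 young agonist-treated, 6 old vehicle-treated and 4 old agonist-treated kidneys. Young mice were 4 months old and old mice 21 months. The deposited table names its 23 libraries by barcode only, and no barcode was matched to a group. The effects of age and of the agonist are therefore not reported, and the values below describe the libraries one by one or as a median and range.

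The table held few reads, and all shares given here are shares of the reads that the table holds. If the values were scaled without transcript length, the total implied by that scaling was a median of 36.2 times larger (range 35.6 to 36.7 times). What that total counts was not established. Whether the table is a complete or sound output of the sequencing was not established either. Dividing each value by the library's step, of which most of its values were whole multiples, gave a median of 1788 reads per library, from 1187 in library 0122 to 4131 in library 0126. A median of 205 genes per library held 1 read or more (range 177 to 297). Over all 23 libraries, 739 of 39072 genes (1.89%) held 1 read or more, and 64 genes held a read in every library. More genes were found in libraries with more reads (Pearson r = 0.73, permutation p = 0.00018; Spearman rho = 0.71, permutation p = 0.00027; 23 libraries; r = 0.88 without libraries 0126 and 0127, the farthest from the median number of reads). This relation was 1 of 2 computed with the number of reads.

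**Figure D1:**
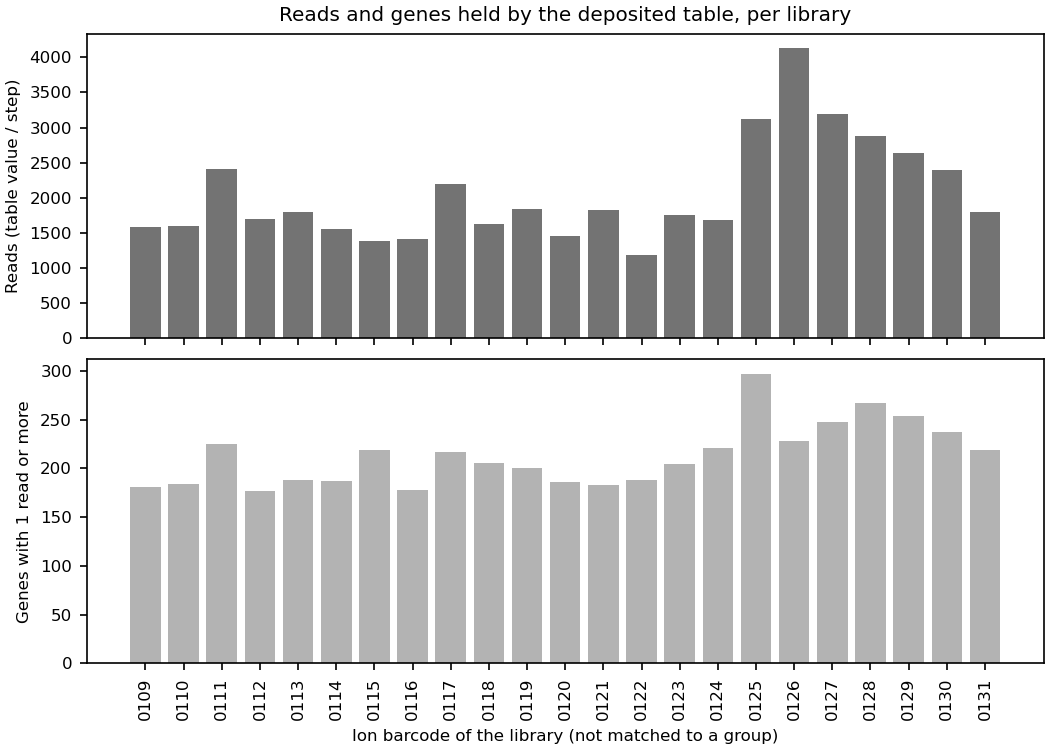
Reads per library (table value divided by the library's step, upper bars) and genes with 1 read or more (lower bars) against the Ion barcode of each library, for the 23 libraries, which were not matched to groups. Reads range from 1187 to 4131 and genes from 177 to 297.

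The largest shares of the reads went to Pck1 and Slc34a1, genes of the proximal tubule (the nephron segment that reabsorbs most of the filtrate), and to the non-coding RNA Rmrp. Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis (chromosome 2, 173153073 to 173159274, mm10), took a median of 27.7% of a library's reads in the table (range 7.75% to 38.1%). Slc34a1, the sodium-phosphate cotransporter of the proximal tubule brush border (chromosome 13, 55399622 to 55414695), took a median of 8.85% (range 4.21% to 11.7%). Rmrp, the RNA component of the RNase MRP ribonucleoprotein (chromosome 4, 43492785 to 43493059), took a median of 9.44% (range 6.82% to 14.2%). Together Pck1, Rmrp and Slc34a1 held 44% of all reads. The 20 genes with the highest median share held 68.3%.

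All 20 held a read in all 23 libraries. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation (chromosome 16, 21761285 to 21787834), had a median share of 3.17% (range 1.96% to 5.30%). Eci3, an enoyl-CoA isomerase (chromosome 13, 34946614 to 34963988), had a median share of 2.03% (range 0.724% to 4.17%). Its lower end was 10 reads in library 0115, without which the lowest share was 1.09%, in library 0125. Rpl32, a protein of the large ribosomal subunit (chromosome 6, 115805514 to 115808743), had a median share of 2.52%. Psmb3, a subunit of the proteasome core (chromosome 11, 97703434 to 97713500), had a median share of 1.98%, and G3bp1, a stress granule protein (chromosome 11, 55469657 to 55500888), had one of 2.01%. Snora16a, a small nucleolar RNA (chromosome 4, 132309465 to 132309600), had a median share of 2.14%. Mgst1, a microsomal glutathione transferase (chromosome 6, 138140527 to 138156755), had a median share of 0.987%, with a range from 0.236% in library 0112 to 4.80% in library 0122. Its lower end rested on 4 reads, and without library 0112 the lowest share was 0.445%, in library 0113. The other members of the 20 (Gm26489, Sacm1l, Ss18l2, Txnl4a, Usp5, Cyb5r3, Rn28s1, Alg1, Hdhd3 and Ltb4r2) had median shares from 0.738% for Ltb4r2 to 1.10% for Gm26489.

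**Figure D2:**
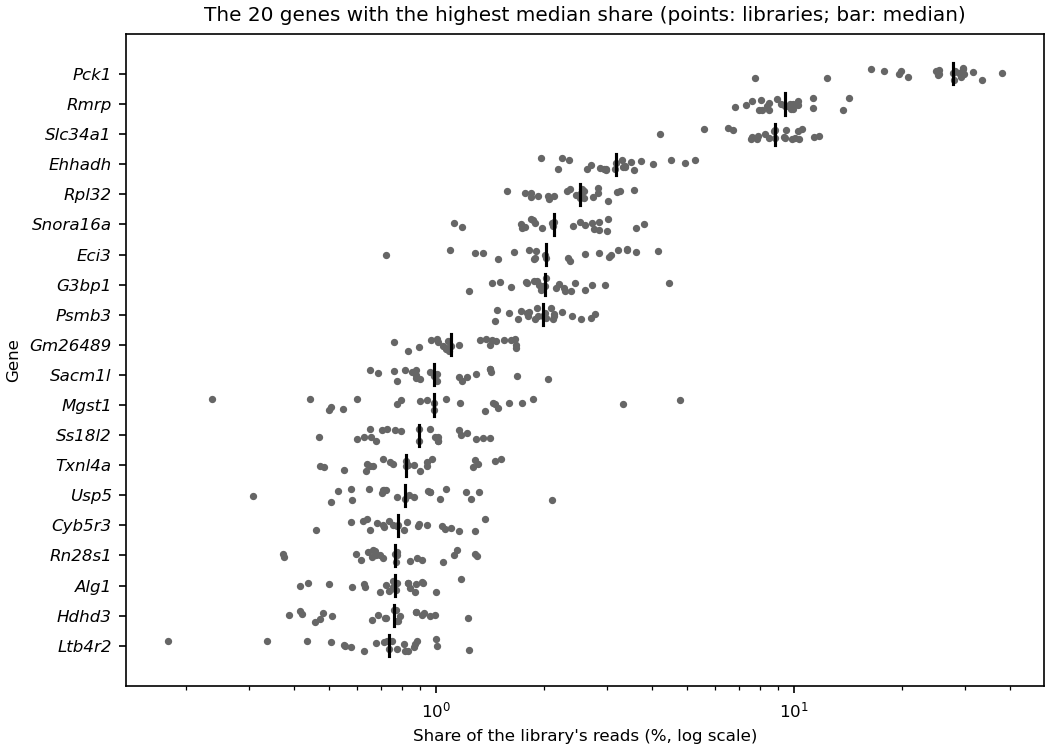
Share of each library's reads (percent, log scale) for the 20 genes with the highest median share. Each point is 1 of 23 libraries and each bar the median over libraries. Pck1 spreads from 7.75% to 38.1% and Mgst1 from 0.236% to 4.80%.

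Messenger RNA rows took a median of 79.8% of the reads (range 71.6% to 84.7%). Small nucleolar and guide RNA rows took 4.25% (range 2.07% to 5.47%), and ribosomal RNA rows 1.29% (range 0.790% to 1.85%). Predicted transcript models took 27% (range 21.1% to 32.7%). For Slc34a1 and Ehhadh, 1 of the 3 and 1 of the 2 transcript rows in the table held all reads of the gene, and in both genes that row was a predicted model. Among the 20 genes with the highest median share, Eci3, G3bp1, Sacm1l, Txnl4a, Cyb5r3 and Alg1 also held all reads in 1 of several rows. The reads of Mgst1 were spread over 5 of its 7 transcript rows, those of Usp5 over 2 of 5 and those of Ltb4r2 over 2 of 3.

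The receptors that the agonist targets were listed at 0. Esrra, Esrrb and Esrrg, and the coactivators Ppargc1a and Ppargc1b, were at 0 in all 23 libraries, as were the other members of the list of 12 receptors and coregulators. Some genes that nearly every cell uses were also at 0. Reported here are 9 such genes, chosen after values had been seen. Of these, 8 (Actb, Gapdh, Ppia, Hprt, Tbp, Tuba1a, Pgk1 and Ywhaz) were at 0 in every library. Eef1a1 held 23 reads over 12 libraries. Other genes of this kind held many reads, Rpl32 (1171 reads) and Psmb3 (942 reads) among them. Umod, Kap, Miox, Lrp2, Cubn, Aqp2, Slc12a1 and Gpx3, abundant kidney genes chosen after values had been seen, were also at 0 in every library. Other abundant kidney genes, Pck1 and Slc34a1 among them, held many reads, and of the 37 proximal tubule genes listed beforehand 6 held a read. A value of 0 in this table is thus reported only as a listed 0, and not as absence of the transcript.

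Most genes of mitochondrial energy metabolism held no read, as did most listed genes of any kind. Over all lists, 55 of 1180 genes (4.66%) held 1 read or more, so these zeros make no statement about mitochondria. Of 36 genes of respiratory complex I, 1 held a read (Ndufc1, 41 reads over all libraries). Of 13 genes of complex IV 2 held a read (Cox6a1 and Cox6b1, 1 read each), and of 17 ATP synthase genes 1 did (Atp5g3, 2 reads). The 4 genes of complex II, the 10 of complex III, the 24 of the TCA cycle and the 22 of the peroxisome list were without reads. Of 32 ERR target genes 2 held reads, Sirt5 (a mitochondrial deacylase) with 43 and Atp5g3 with 2. Of 78 mitochondrial ribosomal protein genes 4 held 1 read or more, led by Mrps12 with 83 reads. Of 29 fatty acid oxidation genes, mitochondrial and peroxisomal together, 2 did. These were Ehhadh, a peroxisomal enzyme that the peroxisome list does not hold, with 1569 reads and Acaa1b with 1.

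Inflammatory and senescence genes were listed at 0 with few exceptions, as were listed genes of any kind, of which 4.66% held 1 read or more. These zeros therefore make no statement about inflammation or senescence. The 11 genes of the cGAS-STING pathway, which senses cytosolic DNA, the 18 of complement and the 20 of senescence held no reads. Of 29 interferon-stimulated genes 4 held reads, led by Ifi27l2a with 14 reads. Of 21 genes of NF-kB and STAT3 signalling Tlr2 alone held reads, with 5 in total. Of 28 cytokines and chemokines Ccl7 and Cxcl10 held 1 read each. Of 15 class I antigen presentation genes, H2-Q6, a member of a family of near-identical genes among which reads can be split, held 51.5 reads. Of the 19 macrophage markers Cx3cr1 held 11 reads. The 21 T and NK cell markers and the 10 neutrophil markers held none.

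Markers of other kidney cells held few reads, as did most of the listed proximal tubule genes and listed genes of any kind. These low numbers therefore make no statement about the cells in the kidneys. Of 37 proximal tubule genes 6 held reads, with Pck1 at 12036 and Slc34a1 at 4169 and no more than 2 reads for each of Keg1, Ttc36, Slc5a2 and Slc7a9. Of 14 distal convoluted and connecting tubule genes 2 held reads, Kcnj16 with 113 and S100g with 9. Synpo, a podocyte actin-binding protein, held 23 reads and was the only one of 17 podocyte genes with a read. No endothelial, collecting duct principal, collecting duct intercalated, adipocyte or red blood cell marker on the lists held a read. In all, 55 of the 1180 listed genes in the table (4.66%) held 1 read or more, and 30 of the 62 lists held none, apart from the list of mitochondrially encoded genes, which matched no row.

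**Figure D3:**
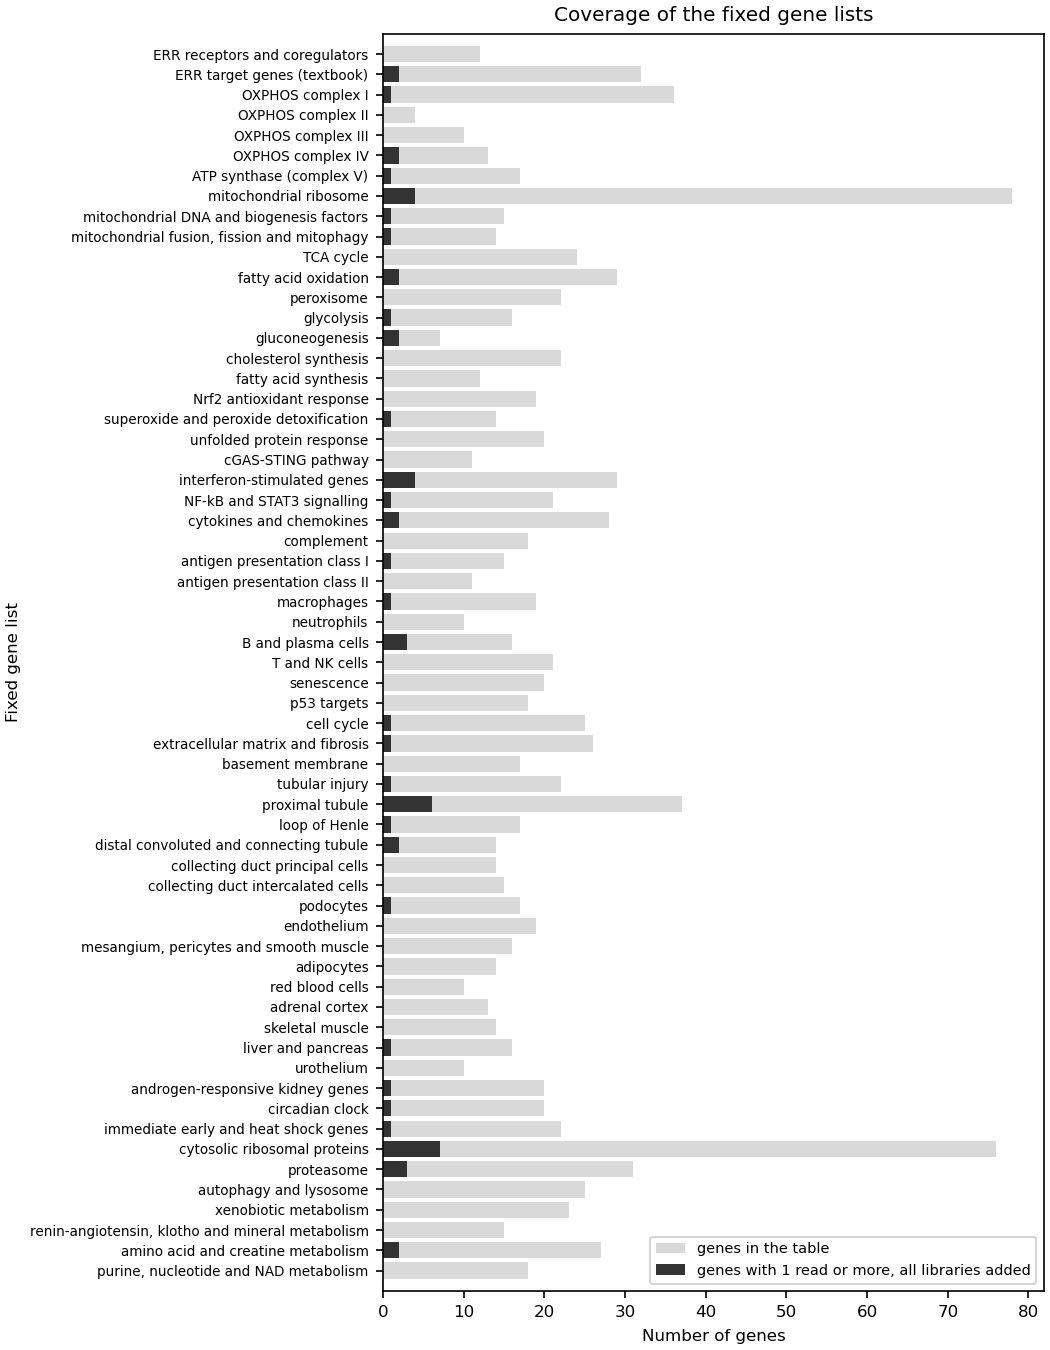
Number of genes (horizontal axis) of each fixed list that are in the table (light bars) and that held 1 read or more with all 23 libraries added (dark bars). The list of 12 ERR receptors and coregulators has no dark bar, and 6 of 37 proximal tubule genes and 7 of 76 cytosolic ribosomal protein genes held a read.

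The libraries differed from each other by more than counting error, which separate animals and amplification without molecular identifiers would exceed in any case. Pck1 had the largest chi-square, 53.7 per degree of freedom, a measure that grows with a gene's reads as well as with its variation (adjusted p = 1.42e-234, chi-square test over 23 libraries). Its share was 7.75% (95% Wilson interval 6.36% to 9.41%) in library 0122 and 38.1% (36.6% to 39.5%) in library 0126. Without library 0122 the lowest share was 12.4%. Mgst1 (11.8 per degree of freedom), Zfp36, an mRNA-decay factor induced early after stimulation (9.37), Rmrp (8.02), Slc34a1 (7.26) and Eci3 (7.25) followed. Of 54 genes tested, 28 varied beyond counting error at an adjusted p under 0.05. Of the 253 pairs of libraries 24 (9.49%) did not differ beyond counting error at an adjusted p under 0.05, and 0 held identical values. With fewer reads this test detects less, so these pairs are not shown to be alike. Every library was kept. The shares of a library are tied to each other, so part of the variation of other genes can follow from that of Pck1. As a share of the reads other than Pck1, Slc34a1 still ran from 4.57% in library 0122 to 15.8% in library 0113. Without library 0122 its lowest such share was 7.69%, in library 0115. How many of the 28 genes varied only because Pck1 did was not tested. Rpl32, by contrast, had a chi-square of 2.16 per degree of freedom (adjusted p = 0.00375), and Psmb3 (adjusted p = 0.188) and Rn28s1 (adjusted p = 0.115) did not pass the threshold.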

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

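The alternatives fixed before the data were examined all concerned comparisons between groups and were not run, because no library was matched to a group. No paired analysis was possible because the columns carry no replicate number of any sample. The alternatives described here were chosen after seeing the data. The median Pck1 share of 27.7% became 33.8% when only messenger RNA rows were used and 30.4% without Rmrp, as the construction of both settings (fewer reads in the denominator) requires. The number of listed genes with a read, 55, fell to 16 when 10 reads over all libraries were required. The count of 28 genes varying beyond counting error lay between 23 and 30 with 1 library left out. It was 23 with messenger RNA rows, 29 with whole values or without Rmrp, and 22 with a minimum mean of 10 reads. The settings with messenger RNA rows and with a mean of 10 reads tested fewer than the 54 genes. Their lower counts are therefore not a lower share of varying genes as such. All other counts and medians stayed within 1.5 times the reported one, and the other Pck1 median within the Wilson interval of the library that holds the median. In the simulation with the numbers of reads of these libraries and Pck1 giving way, the test called 10% of 10 genes changed 1.5-fold, 90% at 2-fold and 100% at 3-fold, and other numbers of reads were not simulated. Without a gene giving way and with 20 changed genes of any share, it called 40%, 65% and 90% of them, and 20 of 33 unchanged genes at 3-fold. The lowest Pck1 share, 7.75%, rested on library 0122 and was 12.4% without it.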

Other observations

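The test of transcript length was set before its result was seen, and all other tests given here were chosen after related values had been seen. Genes other than the 20 with the highest median share also differed between libraries, and those named here were chosen after their values were seen. Zfp36, which encodes an mRNA-decay factor, had a median share of 0.556%, with a range from 0.213% in library 0116 to 2.32% in library 0126. Without library 0126 the highest Zfp36 share was 1.54%, in library 0125. Ddit4, a stress-induced inhibitor of mTORC1, had a median share of 0.336%, with a range from 0.0686% in library 0120 to 1.09% in library 0125. The lower end was 1 read, and without library 0120 the lowest share was 0.177%, in library 0112. The histone gene H2ac24 had its highest share, 2.0%, in library 0115, against a median of 0.491%. Histone genes share near-identical sequence, so their reads can be split or misassigned between copies. Tyms, the thymidylate synthase of DNA synthesis, was the only one of 25 cell cycle genes with a read (224 reads, median share 0.494%).

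Each library's Pck1 share is given here because no library was matched to a group. It was 29.8% in library 0109, 28% in 0110, 29.6% in 0111, 33.5% in 0112, 28% in 0113, 28.8% in 0114, 12.4% in 0115, 27.7% in 0116, 25.3% in 0117, 29.5% in 0118 and 29.2% in 0119. It was 25.3% in 0120, 31.6% in 0121, 7.75% in 0122, 24.8% in 0123, 29.4% in 0124, 16.4% in 0125, 38.1% in 0126, 25.4% in 0127, 19.8% in 0128, 20.7% in 0129, 17.8% in 0130 and 19.6% in 0131. Pck1 share showed no clear relation with reads per library (Pearson r = 0.17, permutation p = 0.45; Spearman rho = 0.08, permutation p = 0.73; r = -0.15 without libraries 0126 and 0127).

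The first pattern weighed is that abundant genes are listed at 0. A low number of reads alone is argued against: 9.21% of the cytosolic ribosomal protein genes (7 of 76, 95% Wilson interval 4.53% to 17.8%) held a read over all libraries, while one of them, Rpl32, held 1171. A loss of reads that fit several transcripts of a gene is not the whole cause either, since 5.02% of the 498 listed genes with a single transcript row held a read (interval 3.42% to 7.31%), against 4.40% of the 682 with several (Fisher's exact test, two-sided, p = 0.676). Transcript length did not separate the genes: the median of the longest reference transcript was 0.88 times as long in the 55 listed genes with a read as in the 1119 without (95% bootstrap interval 0.66 to 1.06, permutation p = 0.3). A mapping or filtering step of the authors that kept only some amplicons stays open as a candidate explanation, and was not tested because read positions were not used here.

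The second pattern is the spread of Pck1 between libraries. Counting error is argued against by the chi-square of 53.743 per degree of freedom (39.8 without library 0126, the lowest value with any 1 library left out). A different share of proximal tubule cells would change Pck1 and Slc34a1 in 1 ratio, and their ratio ran from 1.52 in library 0130 to 5.29 in library 0118, with a chi-square of 15.884 per degree of freedom (11.9 without library 0126). The reads other than Pck1 differed as well, with a chi-square of 2.487 per degree of freedom against at most 1.14 in 1000 simulated sets (p = 0.001, the smallest they can give). These comparisons, that of the Pck1 reads included, are with counting error alone. Separate animals and amplification without molecular identifiers would exceed it in any case, so a different share of tubule cells and a change of Pck1 alone stay open. Age, the agonist, feeding state and time of harvest could each act on Pck1 and were not tested, because the libraries were not matched to groups.

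The third observation is about the unit. The quotient of 1e9 and the step was a whole number, within the rounding of the step, in 22 of the 23 libraries (all but library 0116), where chance would give 1.41. Its range was 42377 to 150523, and it was a median of 36.2 times (range 35.6 to 36.7 times) the reads held by the table. What total it counts was not established, so the table is not shown to hold all reads that entered the scaling. Transcripts within 0.01 of 1 step had reference lengths from 86 to 13934 nt. The step of a library was the same for all of these, so the values did not scale with transcript length as FPKM would.

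Across libraries, 666 pairs among 37 genes with at least 200 reads in total were tested for correlation of their share of the reads other than Pck1, and 0 pairs passed an adjusted p of 0.05 by both Pearson's and Spearman's coefficient. The pair with the largest absolute Spearman coefficient was Eci3 and Mgst1 (r = -0.73, permutation p = 7e-05, adjusted p = 0.047; rho = -0.73, permutation p = 0.00012, adjusted p = 0.08; r = -0.68 without libraries 0115 and 0125). The libraries left out were chosen by Eci3 and not by Mgst1, so library 0122, with the highest Mgst1 share (4.80%), was kept. The groups of these libraries were not told apart, and at least 1 library has no described sample, so such a relation can reflect the groups as well as variation within them.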
